A study of Mus musculus with 12 samples.

How the data were processed

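The data are RNA sequencing of 12 libraries from B16F10 cells with sgRosa26, sgTraf3-1 or sgTraf3-2, each under vehicle or IFNγ at 1 ng/ml for 2 days. Per the labels' protocols, total RNA was isolated and a commercial provider made messenger RNA libraries and sequenced paired reads on an Illumina HiSeq instrument. The submitters' processing notes name STAR, RSEM, DESeq2 and the genome build mm10, without roles or versions, and the annotation is not given in the sources used here. The authors deposited a table of raw counts for 15076 genes by symbol. Its values are whole numbers with totals that differ between libraries, but they may be RSEM estimates rounded to whole numbers, since the notes do not say which tool counted. Whether counting used strand is likewise not given in the sources used here. The authors also deposited a normalized table for 12314 of these genes, with values from 5.06 to 18.4 on a log2 scale. Its form is that of a variance-stabilizing transformation, which is not stated, and its values correlated with log2 CPM at r = 0.986 across genes and libraries. Each column name matched a single sample's labels, and 0 columns were left unmapped.

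All main results were computed from the deposited counts. Genes were filtered with filterByExpr on the 6 groups, which kept 12853 genes, and libraries were scaled with TMM factors. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with a coefficient per group and no other covariate to all 12 libraries, which leaves 6 residual degrees of freedom. Adjusted p-values are those of the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Comparisons were Traf3 guides (mean of both) against sgRosa26 under vehicle and under IFNγ, IFNγ against vehicle in control cells and in Traf3-guide cells, the interaction, each guide alone, and the guides against each other. Values are given as CPM on TMM-scaled library sizes with SD, and fold changes as log2 ± SE. Where every library of a group was at 0, a lower bound was computed against a floor of 3 counts per library. With 1 to 3 counts in a group, the ratio of counts is given with its counting interval. Transcript length, GC content and positions came from GENCODE M21 (the same build, mm10), which gave lengths for 12723 of the genes tested.

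Gene lists were tested with camera (limma 3.58.1) on log2 CPM values with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, adjusted over the 21 lists within each of 5 comparisons, and again with an estimated correlation. The lists, fixed before the data were examined together with the groups, tests, alternatives and the rule for named genes, were MHC-I antigen presentation, MHC-II and its regulators, immune checkpoint ligands, NF-κB pathway components, NF-κB target genes, IFNγ signalling and response, type I interferon-stimulated genes, TNF receptor superfamily and ligands, constitutive proteasome, melanocyte differentiation, neural crest-like melanoma, cell cycle, apoptosis, p53 targets, hypoxia and glycolysis, unfolded protein response, cholesterol synthesis, and markers of immune cells, fibroblasts, endothelial cells and keratinocytes. The list counts adjusted over the list alone use the members' p-values only.

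Genes were named by a rule. Traf3, H2-K1, H2-D1, B2m, Tap1, Nlrc5, Cd274, Nfkb2, Relb, Birc3 and Irf1 were given in each of the 5 comparisons. Some genes that this rule or the list rule below selects are not reported here. In each of these, the 6 genes with the highest and the 6 with the lowest log2 fold change were taken among those called with a mean log2 CPM of at least 1 and, except for the interaction, with no overlap between the libraries of the sides compared, leaving out predicted and unnamed genes. From each list described, up to 4 called members with the smallest adjusted p could be named, or up to 2 where none was called. For the guides against each other, the 3 highest and 3 lowest were taken. Ccne2, as one of a pair of calls, falls under the list rule as well.

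The alternatives were DESeq2 size factors or upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter or a stricter filter (1 CPM in every library of a group), a replicate block, a model of 4 groups with the guides as replicates, only the compared groups, a fold threshold of 1 in log2, each guide alone, and each library left out in turn. A limma-trend fit used the deposited log2 table. It had been set out for log2(value + 1), but the values were already logged and were used directly. After seeing the data, offsets removing each library's trend with length and GC (natural splines with 5 degrees of freedom each), fits without the IFNγ libraries labelled sgTraf3-2, and thinning to the smallest total were added. When a library is left out, the lone sample of its group is assumed to vary like the other groups.

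The scripts were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 of 12853 genes changed. For Traf3 guides under vehicle, 71.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 14 false calls. For the interaction the shares were 53.7%, 82.1% and 98.5%, with 10 false calls. A list of 22 genes shifted by 0.5 in log2 had an adjusted p of 5.15e-36 in the camera test, and 0 other lists were called. Such draws hold no correlation between genes, and so no trend with length or GC as in the real libraries. They therefore do not show how often lists or genes are falsely called in the real data. Shared-control overlaps were set against 20 draws of unchanged groups.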

Results

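Messenger RNA was sequenced from B16F10 cells, an established mouse melanoma line, carrying a guide RNA against the Rosa26 locus (sgRosa26, control) or 1 of 2 guide RNAs against Traf3 (sgTraf3-1 and sgTraf3-2). TRAF3 is an adaptor protein that restrains non-canonical NF-κB signalling by promoting turnover of the kinase NIK. Cells received vehicle or the cytokine IFNγ at 1 ng/ml for 2 days, which gave 6 groups of 2 libraries, 12 libraries in all. The series asks how TRAF3 relates to the expression of MHC-I, which presents antigen to T cells, and of PD-L1, an inhibitory ligand encoded by Cd274. Library totals ran from 17547549 to 24437978 counts, and 14445 to 14666 genes were detected per library. A floor of 3 counts corresponded to 0.120 to 0.185 CPM (counts scaled to a common library size), depending on the library. Floors cover counting error only. Replicates of a group correlated across genes at a Pearson r of 0.988 to 0.990 on log2 CPM values, genes not being independent replicates, and a chi-square over degrees of freedom of 4.63 to 11.02 separated every pair from sampling noise. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

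The libraries also differed in measures that carry no group label. Mitochondrially encoded genes took 1.60 ± 0.0847% of counts in control vehicle libraries and 2.42 ± 0.179% in the IFNγ libraries labelled sgTraf3-2 (SD, n = 2 each), the highest group mean. The Spearman correlation across genes between transcript length and a library's deviation from the mean profile was 0.449 and 0.197 in the control vehicle libraries and −0.420 and −0.408 in the IFNγ libraries labelled sgTraf3-2. Under vehicle it was 0.0930 and 0.153 with sgTraf3-1 and 0.392 and 0.212 with sgTraf3-2, and under IFNγ 0.270 and 0.00689 in control and −0.186 and −0.270 with sgTraf3-1, so replicates differed widely in some groups. Short transcripts were thus relatively more abundant in both IFNγ groups with Traf3 guides.

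**Figure D1:**
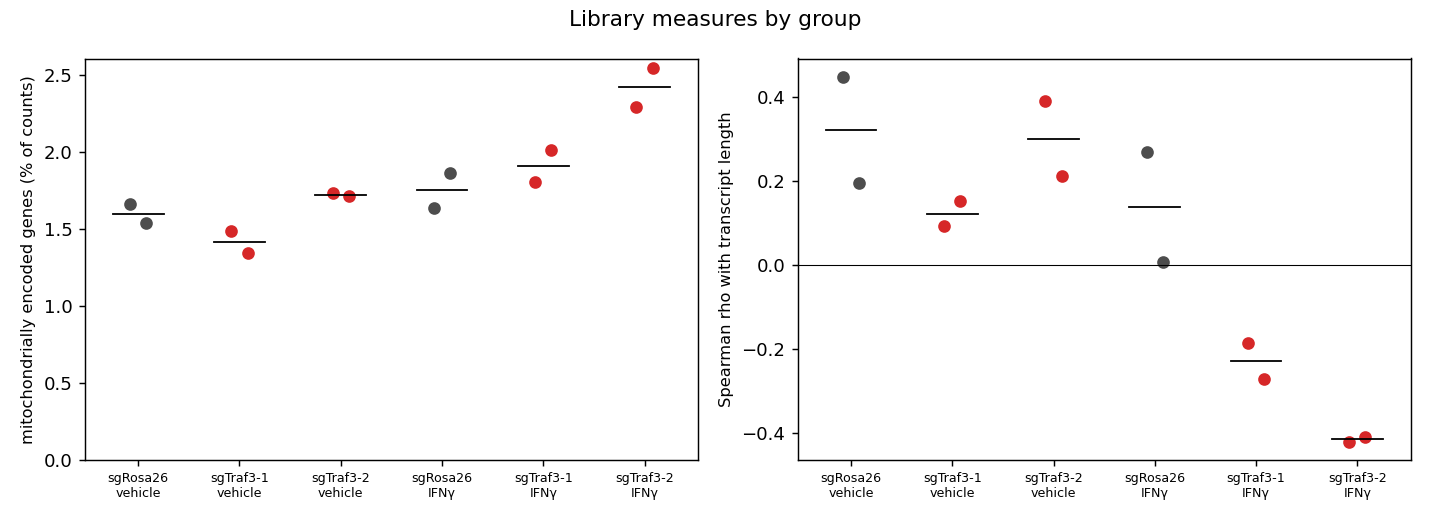
Share of counts from mitochondrially encoded genes (left, percent) and Spearman correlation across genes of each library's deviation from the mean profile with transcript length (right), for each of the 12 libraries by group. The IFNγ libraries labelled sgTraf3-2 lie highest in mitochondrial share (mean 2.42%) and lowest in the correlation with length (mean −0.414).

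Traf3 itself (chromosome 12, 111166370 to 111267153, plus strand, mm10) stood at 89.5 ± 10.4 CPM in control vehicle libraries and 71.5 ± 1.09 CPM in control IFNγ libraries (SD, n = 2). It was lower in the libraries labelled sgTraf3-1, at 45.2 ± 1.97 CPM under vehicle and 35.2 ± 1.10 CPM under IFNγ (log2 fold changes −0.99, adjusted p = 6.95e-05, and −1.02, adjusted p = 4.52e-05). The libraries labelled sgTraf3-2 held 114.5 ± 8.57 and 75.7 ± 11.6 CPM, with log2 fold changes of 0.35 (adjusted p = 0.0743) and 0.09 (adjusted p = 0.523). The guides differed from each other in Traf3 mRNA under vehicle (−1.34 for sgTraf3-1 minus sgTraf3-2, adjusted p = 2.03e-05) and under IFNγ (−1.11, adjusted p = 0.000305). Traf3 mRNA thus gave no sign of Traf3 loss in the libraries labelled sgTraf3-2, although an edit in a coding exon need not lower the mRNA. Over both guides, the Traf3 log2 fold change was −0.32 ± 0.0874 (SE) under vehicle (adjusted p = 0.0664) and −0.47 ± 0.0890 under IFNγ (adjusted p = 0.000896). The vehicle value passed the threshold without control vehicle replicate 2 (−0.44) and without either IFNγ replicate labelled sgTraf3-2 (−0.32 each), and it was −0.20 without control vehicle replicate 1; adjusted p ran from 0.0242 to 0.936 over its alternatives.

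**Figure D2:**
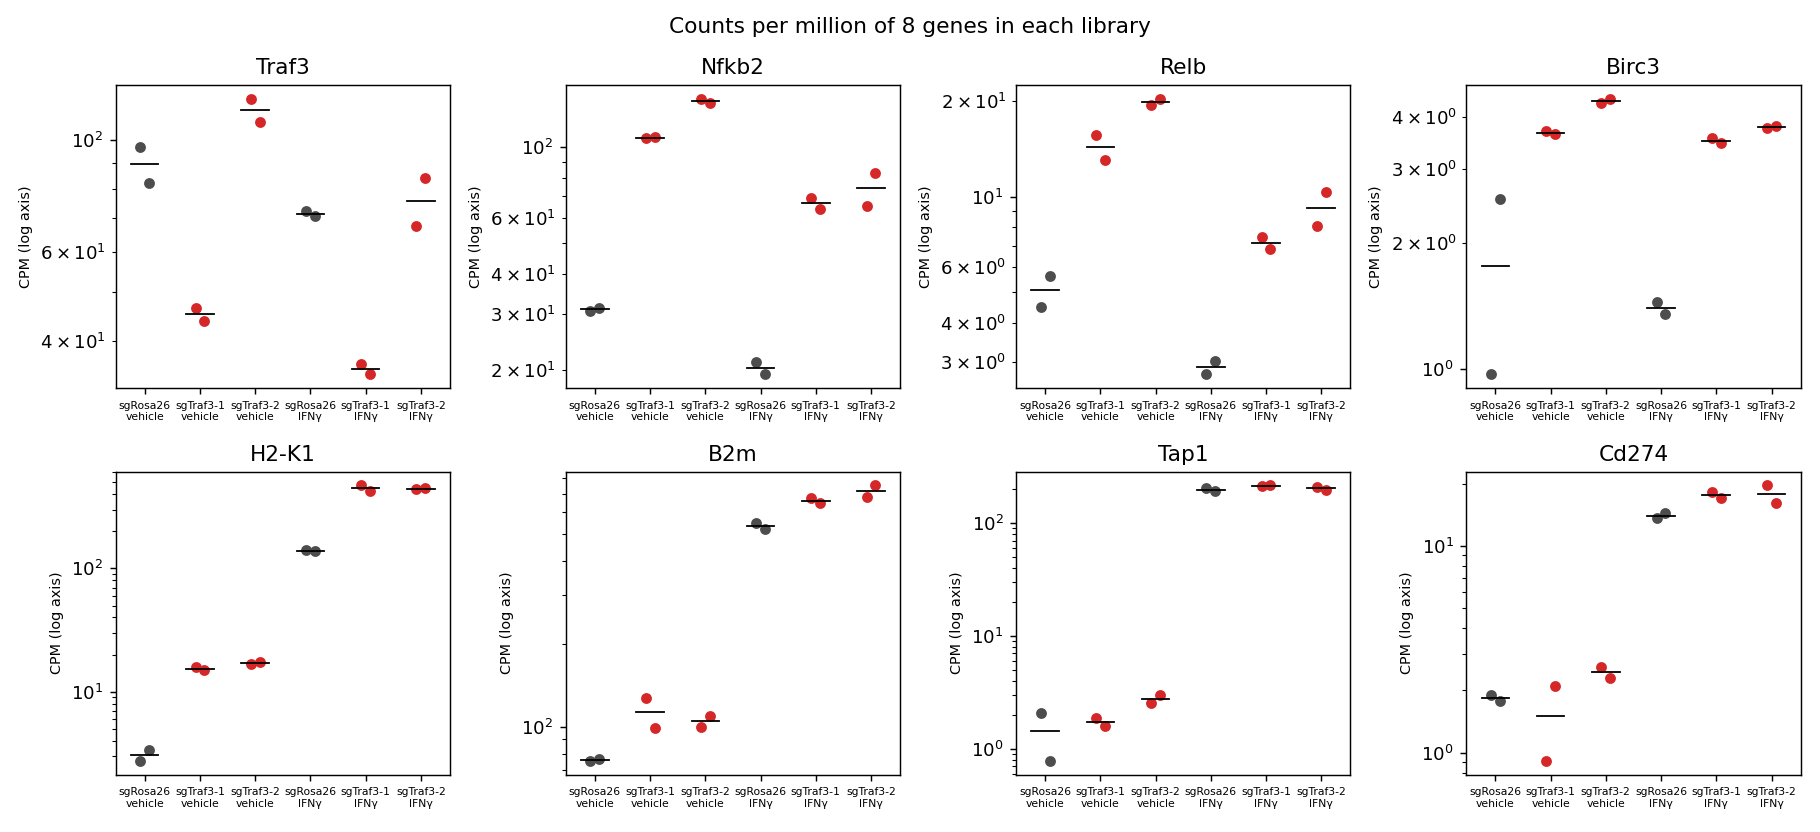
CPM (log axis) of Traf3, Nfkb2, Relb, Birc3, H2-K1, B2m, Tap1 and Cd274 in each of the 12 libraries, with a bar at each group's mean (n = 2). Traf3 is low in the libraries labelled sgTraf3-1 and not in those labelled sgTraf3-2, while H2-K1 and Nfkb2 are raised with both guides; Cd274 under IFNγ lies at 14.01 CPM in control and 17.7 CPM in Traf3-guide libraries.

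Under vehicle, the classical MHC-I heavy chain gene H2-K1 (chromosome 17, 33996017 to 34000347, minus strand, mm10) rose 5.32-fold with the Traf3 guides. It went from 3.07 ± 0.449 CPM (SD, n = 2) to 16.2 ± 1.10 CPM (n = 4), a log2 fold change of 2.41 ± 0.108 (SE, adjusted p = 3.45e-09). Tapbp, which encodes the peptide-loading chaperone tapasin, rose 2.69-fold (adjusted p = 1.36e-08), H2-D1 1.53-fold (adjusted p = 6.5e-05) and B2m, the MHC-I light chain, 1.44-fold (adjusted p = 0.00256). Cd274 did not pass the test, at 1.84 ± 0.0943 CPM in control (n = 2) and 1.98 ± 0.741 CPM in Traf3-guide libraries (n = 4). Its log2 fold change was 0.08 ± 0.246 (adjusted p = 0.909), and −0.31 without replicate 2 labelled sgTraf3-1 under vehicle. Nfkb2, which encodes the p100 precursor of the non-canonical pathway, rose 3.94-fold from 31.02 ± 0.478 to 123 ± 18.8 CPM (adjusted p = 3.45e-09). These directions rest partly on the libraries labelled sgTraf3-2, whose Traf3 mRNA was not lower. The comparison takes the mean of both guides against sgRosa26, and for H2-K1 the guides stood at 15.3 ± 0.592 CPM (sgTraf3-1) and 17.1 ± 0.278 CPM (sgTraf3-2).

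Of 12853 genes tested, 411 passed an adjusted p of 0.05 under vehicle, 234 of them higher and 177 lower with the Traf3 guides. The count was 169 with the guides taken as replicates of a genotype and 620 with each library's trend with length and GC content taken out. With the guides as replicates 14 of 70 named genes lost their call, Birc3 and Cd276 among them. Among called genes with a mean log2 CPM of at least 1, the largest increases were in Frmpd1, at 0 counts in control libraries and at least 105-fold higher with the Traf3 guides, and Stum, which rose 113-fold from 0.378 to 43.5 ± 8.16 CPM. Ttn (titin, 11.1-fold), Ndnf (9.53-fold) and Btn2a2, a butyrophilin (8.06-fold), followed, with Tnfrsf14, which encodes a TNF receptor family member, at least 3.01-fold higher from 0 counts in control. The largest decreases among them were in Carmil2, a regulator of actin capping (log2 fold change −3.02 ± 0.196), Fscn1, the actin bundler fascin (−1.92 ± 0.133), Kif26b (−1.76 ± 0.189), Shisa2 (−1.51 ± 0.233), Mbp (−1.50 ± 0.0996) and Podxl2 (−1.35 ± 0.317). The count of 411 fell to 142 without control vehicle replicate 1, to 220 without replicate 2 labelled sgTraf3-1 and to 238 without replicate 2 labelled sgTraf3-2, all under vehicle. The Tnfrsf14 call ended without control vehicle replicate 1, and the Podxl2 call ended without either control vehicle replicate (−1.56 and −1.12), either replicate labelled sgTraf3-1 (−1.30 and −1.42) or replicate 2 labelled sgTraf3-2 (−1.20). With each guide alone, 206 genes (sgTraf3-1) and 386 genes (sgTraf3-2) passed, and 156 passed with both in the same direction, 116 higher and 40 lower. Both of these comparisons use the same control vehicle libraries, which favours agreement. That shared count was 74 without control vehicle replicate 1, 75 and 76 without replicates 1 and 2 labelled sgTraf3-1, and 99 without replicate 2 labelled sgTraf3-2.

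Among the gene lists, MHC-I antigen presentation rose with the Traf3 guides under vehicle. Of 22 tested members 10 were higher and 0 lower, with 14 higher and 1 lower adjusted over the list alone (median log2 fold change 0.54, adjusted p = 2.74e-14; adjusted p = 0.0107 with an estimated correlation). H2-Q4 reached 1.42 ± 0.116 in log2 fold change. Within the list, Tap1, the peptide transporter subunit, was at 0.55 ± 0.251 (adjusted p = 0.297) and Nlrc5, the MHC-I transactivator, at 1.45 ± 0.387 (adjusted p = 0.0559). Tap1 passed without control vehicle replicate 1 (1.46), and Nlrc5 without any 1 of the IFNγ replicates of control (1.45 each) or sgTraf3-2 (1.46 and 1.45), with adjusted p from 0.00616 to 0.338 over its alternatives. NF-κB pathway components rose as well, with 10 of 23 higher and 0 lower (13 and 1 adjusted over the list alone; median 0.36, adjusted p = 1.81e-13; adjusted p = 0.00445 with an estimated correlation). Map3k14, which encodes NIK, rose 5.32-fold from 3.93 ± 0.113 to 20.9 ± 1.60 CPM, Relb rose 3.36-fold, and the inhibitor gene Nfkbie had a log2 fold change of 2.10 ± 0.105. Birc3, an E3 ligase gene of the TRAF complex, rose by 1.22 ± 0.287 (adjusted p = 0.0288), a call that ended without control vehicle replicate 1 (0.64) or without any 1 of the 4 vehicle replicates with Traf3 guides (1.20 to 1.22). It was 2.03 without control vehicle replicate 2. Of 11 NF-κB target genes 3 were higher (median 0.45, adjusted p = 0.0582), among them Csf1 (0.77 ± 0.0929). That list passed with any 1 library left out (adjusted p from 0.00116 to 0.0137). The filter on low counts is looser in those fits, with 12 or 13 of these genes tested.

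The list of IFNγ signalling and response genes was also raised under vehicle by the Traf3 guides. It had 8 of 32 members higher and 0 lower (9 and 1 adjusted over the list alone; median 0.26, adjusted p = 0.00122; adjusted p = 0.0294 with an estimated correlation). Irf1, a transcription factor of the interferon response, rose by 0.95 ± 0.124 (adjusted p = 0.000321), the receptor gene Ifngr2 by 0.77 ± 0.0731 and the chemokine gene Cxcl10 by 1.15 ± 0.110. In the unfolded protein response list 6 of 22 genes were higher (13 adjusted over the list alone; adjusted p = 1.53e-08; adjusted p = 0.0294 with an estimated correlation). Of these, Trib3 (0.43 ± 0.0765) did not pass without control vehicle replicate 1 (0.42). Among 19 p53 targets 4 were lower and 1 higher (7 and 2 adjusted over the list alone; median −0.18, adjusted p = 0.002; adjusted p = 0.0379 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, stood at −0.32 ± 0.0610 (adjusted p = 0.00679) and did not pass without control vehicle replicate 1 (−0.31). The constitutive proteasome list passed (adjusted p = 0.0125) with 0 of 24 members called, but not with an estimated correlation (adjusted p = 0.647). It did not pass without control vehicle replicate 1 (adjusted p = 0.750) or replicate 2 labelled sgTraf3-2 under vehicle (adjusted p = 0.0998), with the length and GC trend taken out (adjusted p = 0.112) or with sgTraf3-2 alone (adjusted p = 0.159).

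Other lists did not pass under vehicle. Immune checkpoint ligands had 2 of 11 members higher and 1 lower (adjusted p = 0.771), with Lgals3, which encodes galectin-3, 2.97-fold higher. Cd276, which encodes B7-H3, fell by 0.54 ± 0.129, and was not called without control vehicle replicate 1 (−0.36), replicate 1 labelled sgTraf3-1 (−0.49) or replicate 2 labelled sgTraf3-2 (−0.49). The TNF receptor superfamily list had 2 of 12 members higher and 1 lower (adjusted p = 0.0644) and passed with sgTraf3-2 alone (adjusted p = 0.0303), and type I interferon-stimulated genes 3 of 32 higher and 1 lower (adjusted p = 0.867). Melanocyte differentiation genes were 1 of 20 each way (adjusted p = 0.867) and neural crest-like genes 2 of 17 higher (adjusted p = 0.176). Of these, Ddx58, which encodes the RNA sensor RIG-I, rose by 1.25 ± 0.133, the receptor tyrosine kinase gene Kit by 1.07 ± 0.149 and Axl by 1.06 ± 0.143. MHC-II and its regulators had 1 of 6 members higher (adjusted p = 0.771), apoptosis 1 of 21 (adjusted p = 0.485) and hypoxia and glycolysis 1 of 24 (adjusted p = 0.996). The cell cycle list (32 tested, adjusted p = 0.996) and the cholesterol list (22 tested, adjusted p = 0.393) had 0 members called. Lists for immune cells (3 tested, adjusted p = 0.771), fibroblasts (5 tested, adjusted p = 0.996), endothelial cells (2 tested, adjusted p = 0.485) and keratinocytes (1 tested, adjusted p = 0.34) had 0 members called as well. Adjusted over the list alone, the counts in these lists moved by at most 2 genes each way. Median and mean differed in sign for the MHC-II (−0.09 and 0.81), checkpoint (−0.06 and 0.46), type I interferon (−0.07 and 0.04) and melanocyte lists (−0.02 and 0.01).

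**Figure D3:**
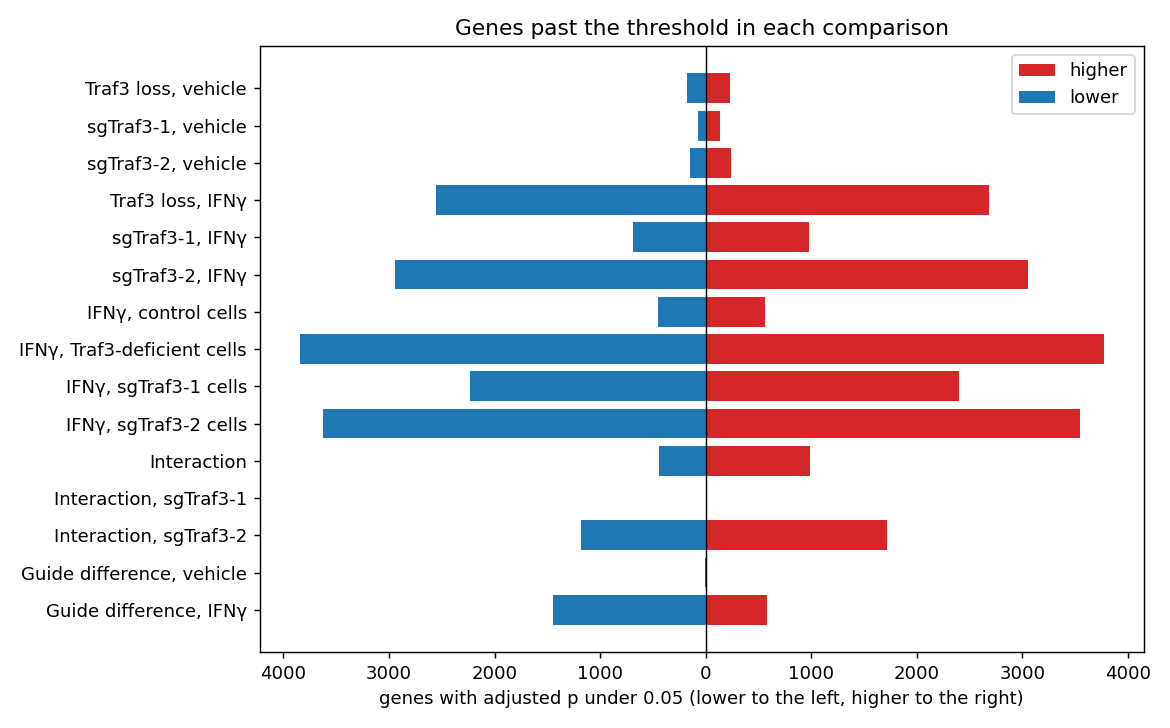
Number of genes past an adjusted p of 0.05 in each comparison (of 12853 tested), drawn to the right for higher and to the left for lower genes. Traf3 loss stands for the mean of both Traf3 guides against sgRosa26, and Traf3-deficient cells for cells with either Traf3 guide. IFNγ in Traf3-guide cells moved the most genes (3772 higher, 3845 lower), and Traf3 guides under vehicle 234 higher and 177 lower. The comparisons differ in their number of libraries, so the counts are not directly comparable.

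Under IFNγ, H2-K1 was again higher with the Traf3 guides, at 446 ± 18.4 CPM (SD, n = 4) against 140 ± 3.41 CPM in control (n = 2), a 3.20-fold difference (log2 1.68 ± 0.0657 SE, adjusted p = 5.32e-10). H2-D1 rose 1.68-fold, from 412 ± 5.15 to 695 ± 25.3 CPM, and B2m 1.28-fold (0.36 ± 0.0814, adjusted p = 0.00295). The B2m value was −0.19 (adjusted p = 0.0863) once each library's trend with transcript length and GC content was taken out, and adjusted p ran from 0.000118 to 0.0863 over its alternatives. Cd274 (chromosome 19, 29367455 to 29388095, plus strand, mm10) stood at 14.01 ± 0.495 CPM in control and 17.7 ± 1.55 CPM with the Traf3 guides, a log2 fold change of 0.34 ± 0.157 that did not pass (adjusted p = 0.0994). It passed with limma-voom (adjusted p = 0.0374), with only the compared groups in the fit (0.0368) and without replicate 1 or 2 labelled sgTraf3-1 under vehicle (0.33 each), and adjusted p ran from 0.0368 to 0.354 over its alternatives. Tap1 (0.07 ± 0.0911, adjusted p = 0.569) and Nlrc5 (−0.20 ± 0.0908, adjusted p = 0.0853) did not pass, while Nlrc5 passed without control IFNγ replicate 2 (−0.36) or IFNγ replicate 2 labelled sgTraf3-2 (−0.29). Nfkb2 rose 3.48-fold (20.2 ± 1.24 to 70.4 ± 8.60 CPM), Relb by 1.49 ± 0.165, Birc3 by 1.38 ± 0.297 (adjusted p = 0.00208) and Irf1 by 0.49 ± 0.0854 (adjusted p = 0.000518). As under vehicle, the libraries labelled sgTraf3-2 enter these means.

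With the Traf3 guides under IFNγ, 5247 genes passed, 2688 higher and 2559 lower, and 256 of them changed at least 2-fold. Of the genes named by size, Frmpd1 was at least 59.3-fold higher from 0 counts in control, Stum 103-fold (log2 6.69, and 7.37 without control IFNγ replicate 1) and Casp4, an inflammatory caspase, 23.6-fold. Serpina3g, a serine protease inhibitor, rose from 0.0452 to 7.42 CPM, a ratio of 160 with a counting interval of 44.2 to 1328, and Ttn and Ndnf rose by 4.71 ± 0.404 and 2.91 ± 0.319. Carmil2 (−3.01 ± 0.207), Fscn1 (−2.38 ± 0.150), Kif26b (−1.96), Shisa2 (−1.74), Myh14 (−1.62) and Mbp (−1.54) had the lowest log2 fold changes. The count was 2431 without control IFNγ replicate 1. With each guide alone 1659 (sgTraf3-1) and 5993 (sgTraf3-2) genes passed, and 1556 passed with both in the same direction, 930 higher and 626 lower. Both of these comparisons use the same control IFNγ libraries, which favours agreement. That shared count was 164 without control IFNγ replicate 1 and 121 without IFNγ replicate 2 labelled sgTraf3-1. The fold changes correlated across genes with transcript length (Spearman rho −0.393).

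In this comparison the MHC-I list had 16 of 22 members higher and 0 lower (16 and 0 adjusted over the list alone; median 0.41, adjusted p = 4.87e-05), but adjusted p = 0.0903 with an estimated correlation. H2-Q4 was at 1.03 and H2-T22 at 0.72. NF-κB components had 13 of 23 higher and 2 lower (13 and 2 adjusted over the list alone; median 0.51, adjusted p = 0.000188; adjusted p = 0.0697 with an estimated correlation), with Map3k14 5.54-fold higher, Nfkbie at 1.99 and Nfkbia at 1.44. The IFNγ response list had 16 of 32 higher and 2 lower (16 and 2 adjusted over the list alone; adjusted p = 0.00162; adjusted p = 0.0697 with an estimated correlation). Cxcl10 rose 3.70-fold, Irf8 by 1.69 ± 0.141 and the GTPase gene Ifi47 by 0.91. Of 24 constitutive proteasome members 19 were higher and 0 lower (20 and 1 adjusted over the list alone; median 0.45, adjusted p = 1.96e-07; adjusted p = 0.334 with an estimated correlation), such as Psma7, 1.66-fold higher. In the unfolded protein response list 15 of 22 were higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p = 7.88e-05; adjusted p = 0.0903 with an estimated correlation), with Sec61b at 0.80 and Atf3 at 1.05. Short transcripts were also raised in these libraries, and the mitochondrial share in those labelled sgTraf3-2.

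The remaining lists did not pass under IFNγ with the Traf3 guides. Checkpoint ligands went both ways, 2 of 11 higher and 2 lower (adjusted p = 0.983), with Lgals3 3.64-fold higher, Cd47, which signals against phagocytosis, at 0.51 and Cd276 at −0.76. Ceacam1 fell by 1.20 (adjusted p = 0.0158), and was not called without control IFNγ replicate 1 (−1.10) or IFNγ replicate 1 labelled sgTraf3-2 (−1.03). Type I interferon-stimulated genes were 5 higher and 3 lower (adjusted p = 0.561), NF-κB targets 2 higher and 0 lower (adjusted p = 0.599) and TNF receptor superfamily genes 4 higher and 1 lower (adjusted p = 0.245). Melanocyte genes were 6 higher and 4 lower (adjusted p = 0.542), and neural crest-like genes 3 and 5 (adjusted p = 0.599). The counts were 9 and 10 for cell cycle genes (adjusted p = 0.666), 8 and 2 for apoptosis genes (adjusted p = 0.425) and 3 and 7 for p53 targets (adjusted p = 0.245), which passed with sgTraf3-1 alone (adjusted p = 0.0152). Hypoxia genes were 2 higher and 4 lower (adjusted p = 0.202), and cholesterol genes 3 and 5 (adjusted p = 0.599). MHC-II genes had 1 of 6 higher (adjusted p = 0.554). Of the marker lists, fibroblast genes had 2 of 5 lower and 1 immune gene, Coro1a, rose by 1.76, a call that ended without control IFNγ replicate 1 (0.97) or IFNγ replicate 1 labelled sgTraf3-1 (1.59), with 3.65 without control IFNγ replicate 2. Adjusted over the list alone, the counts in these lists moved by at most 2 genes each way, and neural crest-like genes had a median of −0.10 and a mean of 0.14.

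In control cells IFNγ raised genes of antigen presentation and PD-L1 expression. H2-K1 rose 45.8-fold, from 3.07 ± 0.449 to 140 ± 3.41 CPM (SD, n = 2 each), H2-D1 8.26-fold and B2m (chromosome 2, 122147686 to 122153083, plus strand, mm10) 7.08-fold, from 75.8 ± 0.686 to 537 ± 19.9 CPM. Tap1 rose 133-fold (log2 7.05, but 7.97 without control vehicle replicate 1 and 6.57 without replicate 2) and Nlrc5 262-fold, from 0.326 to 87.1 ± 12.7 CPM. Cd274 rose 7.58-fold, from 1.84 ± 0.0943 to 14.01 ± 0.495 CPM (log2 2.92 ± 0.227 SE, adjusted p = 2.55e-07). Irf1 rose 18.7-fold. Nfkb2 fell by 0.62 ± 0.106 (adjusted p = 0.00196) and Relb by 0.80 ± 0.192 (adjusted p = 0.0200), the latter call ending without control vehicle replicate 2 (−0.64) or control IFNγ replicate 1 (−0.74) or 2 (−0.87). Birc3 (−0.30, adjusted p = 0.661) and Traf3 (−0.33 ± 0.102, adjusted p = 0.0628) did not pass, though Traf3 did without control vehicle replicate 2 (−0.44) or either IFNγ replicate labelled sgTraf3-2 (−0.32 each). The Birc3 value was 0.52 without control vehicle replicate 2.

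IFNγ moved 1012 genes in control cells, 565 higher and 447 lower, of which 165 rose and 22 fell at least 2-fold. The count was 369 with the guides taken as replicates of a genotype and 619 with only the compared groups in the fit, where 29 of 80 and 11 of 79 named genes lost their call, Relb, Hes1 and Postn in both. From 0 counts in control vehicle libraries, the interferon-inducible GTPase genes Tgtp1 and Iigp1 were at least 4021-fold and 1327-fold higher, the immunoproteasome gene Psmb8 at least 212-fold and the transcription factor gene Irf8 at least 67.9-fold. Tgtp2 (log2 12.78 ± 0.182) and Igtp (11.10 ± 0.160) were next, at 11.98 and 10.44 without control vehicle replicate 1 and 14.13 and 12.001 without replicate 2, and Tgtp1 and Tgtp2 are near-identical copies whose reads the counting may have split, so their values are uncertain. Across genes, fold changes in this comparison correlated negatively with transcript length (Spearman rho −0.260). The genes named by size with the lowest log2 fold changes were Ttn (−2.10), Zfp469 (−1.56), Neb (−1.54), Mmp15 (−1.51), the Notch target Hes1 (−1.32) and Col1a1 (−1.29). Of these, Ttn was not called without control vehicle replicate 2 (−1.58), control IFNγ replicate 1 (−2.69) or 2 (−1.69) or either IFNγ replicate labelled sgTraf3-1 (−2.10 each), and Mmp15 without control vehicle replicate 1 (−1.21) or control IFNγ replicate 1 (−1.12). Hes1 was not called without control vehicle replicate 1 (−1.51) or 2 (−1.13) or control IFNγ replicate 1 (−0.98). Zfp469 (−1.38), Neb (−1.24) and Col1a1 (−1.23) were not called without control IFNγ replicate 2. The count was 424 without control vehicle replicate 1 and 311 without control IFNγ replicate 2.

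By list, 18 of 22 MHC-I members rose with IFNγ in control cells and 0 fell (20 and 0 adjusted over the list alone). The median log2 fold change was 3.74, or 3.60 with genes at 0 in control set at their bound (adjusted p = 2.12e-38; adjusted p = 0.000461 with an estimated correlation). The IFNγ response list had 24 of 32 higher (24 adjusted over the list alone; median 4.35, or 4.12 at the bounds; adjusted p = 1.57e-36). Type I interferon-stimulated genes had 29 of 32 higher (30 adjusted over the list alone; adjusted p = 4.35e-43). In neither did any gene fall, and both passed with an estimated correlation (adjusted p = 0.000133 and 0.000194). Examples were Tapbp (18.5-fold), Gbp2 (7.08 ± 0.104 in log2), Bst2 (3.31) and Irf9 (3.33). Of 11 checkpoint ligands 4 rose (4 adjusted over the list alone; adjusted p = 0.00235; adjusted p = 0.0513 with an estimated correlation), including Tnfrsf14, at least 23.3-fold from 0 counts, and Lgals9 (0.58). Of 19 p53 targets 10 fell and 0 rose (12 and 0 adjusted over the list alone; median −0.38, adjusted p = 2.88e-07; adjusted p = 0.00571 with an estimated correlation), with Cdkn1a at −0.65 ± 0.0718 and Zmat3 at −0.75. Proteasome genes were 12 of 24 higher (16 adjusted over the list alone; adjusted p = 4.31e-08; adjusted p = 0.200 with an estimated correlation). Melanocyte genes had 7 of 20 higher (9 higher and 2 lower adjusted over the list alone; adjusted p = 0.000921; adjusted p = 0.0771 with an estimated correlation), among them Trpm1, a cation channel gene (1.22 ± 0.0784). Cholesterol genes had 4 of 22 higher (8 adjusted over the list alone; adjusted p = 0.000921; adjusted p = 0.0321 with an estimated correlation). Apoptosis genes were 5 of 21 higher (6 and 2 lower adjusted over the list alone; adjusted p = 0.0124; adjusted p = 0.0706 with an estimated correlation), with Mlkl at 1.25 and Bid at 1.00.

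Neural crest-like genes fell with IFNγ in control cells. They had 7 of 17 lower and 0 higher (10 and 1 adjusted over the list alone; median −0.37, adjusted p = 0.000144; adjusted p = 0.155 with an estimated correlation), with Pdgfrb at −0.99 and Cyr61 at −0.84. Fibroblast markers passed with 2 of 5 lower, Col1a1 and Postn (adjusted p = 0.0281; adjusted p = 0.282 with an estimated correlation), but not without control vehicle replicate 1 (adjusted p = 0.0598) or control IFNγ replicate 2 (adjusted p = 0.405), nor with the length and GC trend taken out (adjusted p = 0.176). Without control IFNγ replicate 2 neither the Col1a1 call (−1.23) nor the Postn call (−0.47) held. NF-κB components had 1 gene higher and 5 lower (adjusted p = 0.128), NF-κB targets 1 each way (adjusted p = 0.714) and TNF receptor superfamily genes 1 each way (adjusted p = 0.978). The lists for cell cycle (1 of 32 higher, adjusted p = 0.767), hypoxia (2 each way, adjusted p = 0.852), unfolded protein response (1 higher, adjusted p = 0.177) and MHC-II (1 higher, adjusted p = 0.517) did not pass. Nor did immune (adjusted p = 0.505), endothelial (adjusted p = 0.517) or keratinocyte markers (adjusted p = 0.852). Counts adjusted over the list alone differed by at most 2 genes each way in the lists that did not pass.

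**Figure D4:**
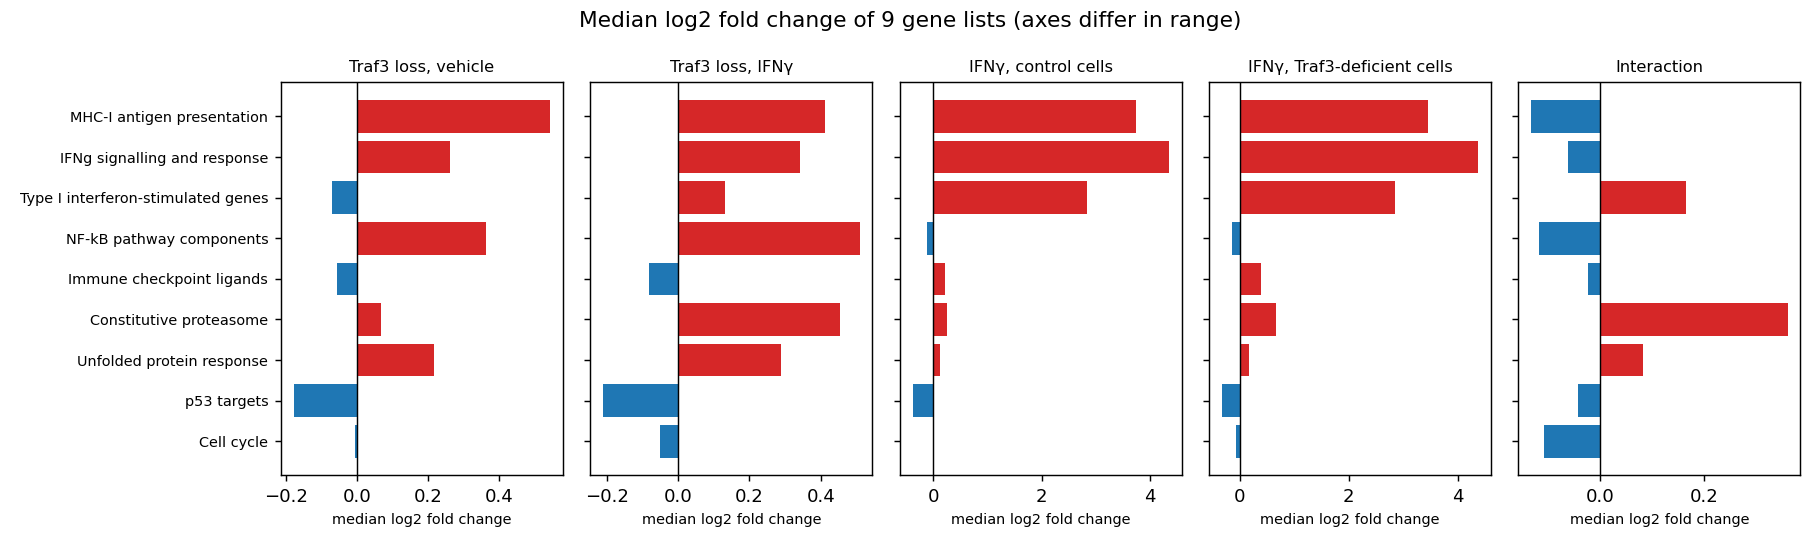
Median log2 fold change of 9 gene lists in the 5 comparisons, as bars from 0 on axes that differ in range. Traf3 loss and Traf3-deficient cells stand for the cells with either Traf3 guide. The MHC-I, IFNγ response and type I interferon lists lie at medians of 3.74, 4.35 and 2.83 with IFNγ in control cells, and MHC-I and NF-κB components at 0.54 and 0.36 with the Traf3 guides under vehicle.

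IFNγ raised antigen presentation genes and Cd274 in cells with Traf3 guides too. H2-K1 went from 16.2 ± 1.10 to 446 ± 18.4 CPM (SD, n = 4 each), 27.5-fold, H2-D1 rose 9.10-fold, B2m 6.33-fold, Tap1 95.4-fold and Nlrc5 82.9-fold. Cd274 rose 9.03-fold, from 1.98 ± 0.741 to 17.7 ± 1.55 CPM (log2 3.18 ± 0.158 SE). Irf1 rose by 3.76 on the log2 scale, Nfkb2 fell by 0.80 ± 0.0660, Relb by 1.05 ± 0.110 and Traf3 by 0.48, and Birc3 was at −0.14 (adjusted p = 0.603). In all 7617 genes passed, 3772 higher and 3845 lower, and 364 rose and 176 fell at least 2-fold. With 4 libraries on each side, this count is not directly comparable with that in control cells, which rests on fewer. The low-count ratios of Iigp1 and Psmb8 were 13917 (counting interval 3852 to 114923) and 1779 (492 to 14698), and Igtp and Gbp6 rose by 11.21 and 10.51, the latter by 11.19 without vehicle replicate 1 labelled sgTraf3-2. Neb (−1.75), Mmp15 (−1.66), the integrin gene Itgb4 (−1.59), Hr (−1.57), Cdc42ep1 (−1.55) and Tns1 (−1.51) were the lowest. Fold changes correlated with transcript length across genes (rho −0.373), and the IFNγ libraries labelled sgTraf3-2, whose Traf3 mRNA was not lower than control, had the highest mitochondrial share.

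Of the lists in Traf3-guide cells, MHC-I had 20 of 22 members higher with IFNγ (20 higher and 1 lower adjusted over the list alone; median 3.45, adjusted p = 4.65e-15; adjusted p = 0.00655 with an estimated correlation). The IFNγ response list was 25 of 32 higher and 3 lower (adjusted p = 2.47e-14) and type I interferon-stimulated genes 31 of 32 higher (adjusted p = 2.09e-17). Proteasome genes were 22 of 24 higher and 1 lower (adjusted p = 6.16e-08; adjusted p = 0.214 with an estimated correlation). Melanocyte genes were 14 of 20 higher and 4 lower (adjusted p = 0.0237; adjusted p = 0.214 with an estimated correlation), a call that ended with the length and GC trend taken out (adjusted p = 0.407) and with sgTraf3-2 alone (adjusted p = 0.0654). Neural crest-like genes were 13 of 17 lower and 1 higher (adjusted p = 0.000699; adjusted p = 0.214 with an estimated correlation). Slc24a5, a pigment exchanger gene of the melanocyte list, was at 0.37. It turned to −0.13 (adjusted p = 0.00835) with the length and GC trend taken out, adjusted p running from 9.52e-17 to 0.00835 over its alternatives. Targets of p53 were 11 of 19 lower and 2 higher (adjusted p = 0.0237; adjusted p = 0.146 with an estimated correlation), not passing without IFNγ replicate 2 labelled sgTraf3-2 (adjusted p = 0.0707) or with sgTraf3-2 alone (adjusted p = 0.0539). Apoptosis genes were 13 of 21 higher and 3 lower (adjusted p = 0.0483; adjusted p = 0.175 with an estimated correlation), a call that ended in 8 of 12 fits with a library left out (adjusted p up to 0.073). Those were the fits without either vehicle or either IFNγ control replicate, either vehicle replicate 2 with a Traf3 guide, IFNγ replicate 1 labelled sgTraf3-1 and IFNγ replicate 2 labelled sgTraf3-2. It also ended with a replicate block (adjusted p = 0.0527) and with sgTraf3-2 alone (adjusted p = 0.0651). Checkpoint ligands (5 higher, 1 lower, adjusted p = 0.124), NF-κB components (3 and 8, adjusted p = 0.119), NF-κB targets (3 and 4, adjusted p = 0.657) and TNF receptor superfamily genes (2 and 2, adjusted p = 0.895) did not pass. Nor did cell cycle genes (11 and 14, adjusted p = 0.681), hypoxia genes (5 and 10, adjusted p = 0.225) or unfolded protein response genes (12 and 5, adjusted p = 0.124). The same held for cholesterol genes (11 and 5, adjusted p = 0.0963), MHC-II genes (3 and 0, adjusted p = 0.2998) and fibroblast markers (0 and 4, adjusted p = 0.0592). Without vehicle replicate 1 labelled sgTraf3-2 or either control IFNγ replicate, fibroblast markers passed (adjusted p = 0.0349, 0.0336 and 0.0336), as they did with sgTraf3-1 alone (adjusted p = 0.0271). With the length and GC trend taken out, the checkpoint (adjusted p = 0.0449), cell cycle (adjusted p = 0.0191) and cholesterol lists (adjusted p = 0.00341) passed, the last also with sgTraf3-1 alone (adjusted p = 0.0292). For the lists of Traf3-guide cells after MHC-I, counts adjusted over the list alone differed by at most 1 gene each way.

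Whether the IFNγ response itself differed with the Traf3 guides was tested as an interaction. The gene with the firmest difference was Tapbp, which rose from 14.9 ± 1.56 to 276 ± 10.3 CPM in control (SD, n = 2) and from 40.1 ± 2.32 to 360 ± 10.6 CPM with Traf3 guides (n = 4). Its interaction was −1.04 ± 0.0972 in log2 (SE, adjusted p = 0.000247). Ddx58 (−1.10 ± 0.166), Parp10, an ADP-ribosyltransferase gene (−1.01 ± 0.137), and Csf1, which encodes a macrophage growth factor (−0.80 ± 0.123), also had smaller IFNγ fold changes with Traf3 guides (adjusted p = 0.0052 each). For H2-K1 the interaction was −0.74 ± 0.130 (adjusted p = 0.00721), lost without control IFNγ replicate 1 (−0.71). For Nlrc5 it was −1.66 ± 0.396 (adjusted p = 0.0188), lost without either control vehicle replicate (−1.72 and −1.61), vehicle replicate 2 labelled sgTraf3-1 (−1.59) or control IFNγ replicate 1 (−1.50). Cd274 showed no difference past the test (0.25 ± 0.293, adjusted p = 0.613). Nor did H2-D1 (0.14, adjusted p = 0.344), B2m (−0.16, adjusted p = 0.386), Tap1 (−0.48, adjusted p = 0.258), or Irf1 (−0.46, adjusted p = 0.0606). The same held for Nfkb2 (−0.18, adjusted p = 0.36), Relb (−0.26, adjusted p = 0.484), Birc3 (0.16, adjusted p = 0.836) and Traf3 (−0.15, adjusted p = 0.462). Without control vehicle replicate 1, Tap1 (−1.40) passed. Irf1 passed without vehicle replicate 2 labelled sgTraf3-1 (−0.56) or replicate 1 labelled sgTraf3-2 (−0.54), and Birc3 was −0.66 without control vehicle replicate 2.

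The interaction called 1433 genes, 989 higher and 444 lower. With the length and GC trend taken out it called 721, and the share that was higher fell from 69.0% to 51.2%, so the excess of higher genes did not hold. With the guides taken as replicates of a genotype it called 1. The count was 25 without control IFNγ replicate 1, 478 without control vehicle replicate 2, 685 and 704 without vehicle replicate 2 labelled sgTraf3-1 and replicate 1 labelled sgTraf3-2, 538 without IFNγ replicate 2 labelled sgTraf3-1 and 2485 without IFNγ replicate 2 labelled sgTraf3-2. It was 2 for sgTraf3-1 alone by edgeR (1548 at an unadjusted p under 0.05), Tapbp (−0.96, adjusted p = 0.00399) and the cyclin gene Ccne2, and 2897 for sgTraf3-2, whose libraries had no lower Traf3 mRNA. The genes named by size on the positive side were Tgtp2 (3.76 ± 1.07), Sp3os (1.40 ± 0.325), the ubiquitin-like modifier gene Isg15 (1.27 ± 0.277), Ifi47 (1.26 ± 0.234), Dlx6os1 (1.24 ± 0.292) and Ptpn18 (1.18 ± 0.302). On the negative side they were Tnfrsf14 (−5.68 ± 1.21), Nlrc5, Lims2 (−1.31 ± 0.374), Ddx58, Tapbp and Parp10. Tgtp2 lay at 1 count in total in the Traf3-guide vehicle libraries and Tnfrsf14 at 0 in control vehicle libraries, so both values depend on the prior count. Sp3os and Dlx6os1 are antisense transcripts that counting without strand could not separate from their partners. Tapbp, Ddx58, Parp10, Csf1 and Ccne2 were called with any 1 library left out, but with the guides taken as replicates of a genotype only Tapbp was called (adjusted p = 0.00204). In that model 43 of 65 named genes lost their call in the interaction, and with the length and GC trend taken out 20 did. The calls of Tgtp2 (3.73), Sp3os (1.31), Isg15 (1.14), Ifi47 (1.17), Dlx6os1 (1.10), Ptpn18 (1.07), Tnfrsf14 (−5.72) and Lims2 (−1.20) ended without control IFNγ replicate 1. Control vehicle replicate 1 also ended those of Isg15 (1.14), Ifi47 (1.10) and Lims2 (−1.16), and replicate 2 those of Tgtp2 (2.42), Sp3os (1.19), Dlx6os1 (1.07), Ptpn18 (0.90), Tnfrsf14 (−5.70) and Lims2 (−1.46). Of the Traf3-guide libraries, vehicle replicate 2 labelled sgTraf3-1 (3.75 and 1.03), vehicle replicate 1 labelled sgTraf3-2 (3.29 and 1.10) and IFNγ replicate 2 labelled sgTraf3-1 (3.74 and 1.08) ended those of Tgtp2 and Ptpn18. Vehicle replicate 1 labelled sgTraf3-1 ended that of Tgtp2 (3.77), and Lims2 (−1.18 to −1.42) was called in 2 of the 12 fits with a library left out.

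Among the lists the interaction passed for the constitutive proteasome, 14 of 24 members higher and 0 lower (17 and 1 adjusted over the list alone; median 0.36, adjusted p = 1.17e-06; adjusted p = 0.818 with an estimated correlation). Examples were Psma5 (0.71), Psmd14 (0.59), Psma7 (0.58) and Psmc6 (0.56 ± 0.0848), whose calls ended without control IFNγ replicate 1 (0.59, 0.54, 0.52 and 0.50). With the length and GC trend taken out 3 of 24 were higher and the median was 0.13 (adjusted p = 0.0370 for the list). With sgTraf3-1 alone 0 members were called by edgeR. In the MHC-I list 1 member was higher and 4 lower (2 and 6 adjusted over the list alone; adjusted p = 0.629), and in the IFNγ response list 3 each way (adjusted p = 0.629). In type I interferon-stimulated genes the count was 1 each way (adjusted p = 0.699), in checkpoint ligands 0 and 1 (adjusted p = 0.836) and in NF-κB components 1 and 0 (adjusted p = 0.629). Melanocyte genes had 4 higher and cell cycle genes 7 higher and 3 lower, and no other list passed. Outside the MHC-I and proteasome lists, counts adjusted over the list alone differed by at most 2 genes each way. Median and mean differed in sign for the IFNγ response list (−0.06 and 0.17) and NF-κB components (−0.12 and 0.01), among others. The IFNγ fold change of the pooled guides includes the IFNγ libraries labelled sgTraf3-2, the group with the lowest mean correlation with length (−0.414).

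The guides were also compared with each other. Under vehicle 10 genes differed, 3 higher and 7 lower in sgTraf3-1 than in sgTraf3-2 by edgeR (1346 at an unadjusted p under 0.05), Traf3 itself among them. More than 35 differed by DESeq2, and also with the length and GC trend taken out. Id3, an inhibitor of helix-loop-helix factors (0.93 ± 0.155, adjusted p = 0.0333), Gjb2 (0.63) and Sparcl1 (0.42) were higher, and AY036118 (−1.64) and Rn7sk (−1.26) lower. AY036118 is annotated as a long non-coding RNA and Rn7sk as a non-coding RNA of 331 nucleotides. The count lay between 2 (without vehicle replicate 1 labelled sgTraf3-1) and 35 (without either control vehicle replicate). It was 6 without vehicle replicate 2 labelled sgTraf3-1, 5 without vehicle replicate 1 labelled sgTraf3-2, and 22 and 24 without IFNγ replicates 1 and 2 labelled sgTraf3-2. The calls of Id3 (0.68), AY036118 (−1.42), Gjb2 (0.65), Sparcl1 (0.43) and Rn7sk (−1.15) ended without vehicle replicate 1 labelled sgTraf3-1, and those of Gjb2 (0.60), Sparcl1 (0.39) and Rn7sk (−1.41) without its replicate 2. Those of Id3 (1.00 and 0.85), Sparcl1 (0.38 and 0.45) and Rn7sk (−1.18 and −1.35) ended without vehicle replicate 1 or 2 labelled sgTraf3-2, and that of Gjb2 (0.59) without its replicate 2. The call ended for Id3 (0.92 each) without either IFNγ replicate labelled sgTraf3-1, and for Sparcl1 (0.41 each) without either control IFNγ replicate.

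Under IFNγ 2027 genes differed between the guides, 585 higher and 1442 lower in sgTraf3-1. Of the proteasome genes 17 were lower and 1 higher (18 and 1 adjusted over the list alone). The genes named by size were Trib2, a pseudokinase gene (1.75 ± 0.422), Slc24a4 (1.29) and AY036118 (1.25) on the higher side, and Fyb, an adaptor gene (−3.69 ± 0.944), Gstk1 (−1.16) and Atp5k, an ATP synthase subunit gene (−1.14), on the lower side. Fyb differed as widely within groups as between them, with 43 and 419 counts in the control vehicle replicates. AY036118 went the other way under vehicle. Under IFNγ its replicates spread widely, at 1556 and 1032 CPM with sgTraf3-1 and 674 and 418 CPM with sgTraf3-2. The count fell to 178 without IFNγ replicate 1 labelled sgTraf3-1 and to 985 without IFNγ replicate 1 labelled sgTraf3-2. The calls of Trib2 (1.55), Slc24a4 (1.17), AY036118 (0.92), Atp5k (−1.01) and Fyb (−3.16) ended without IFNγ replicate 1 labelled sgTraf3-1, that of Fyb also without its replicate 2 (−4.53), and those of Trib2 (1.27) and Fyb (−2.98) without IFNγ replicate 2 labelled sgTraf3-2.

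Genes moved by the Traf3 guides under vehicle moved the same way under IFNγ in most cases. Of the 234 genes higher under vehicle 183 were also higher under IFNγ (48.9 for independent lists), of the 177 lower 141 were also lower (35.2), and 1 went the opposite way, in comparisons with no library in common. Across guides, 120 of 138 genes higher with sgTraf3-1 under vehicle were higher with sgTraf3-2 under IFNγ (32.8 for independent lists), 57 of 68 lower genes were lower (15.6), and 3 were opposite (r = 0.370 across genes, covariance 0.118). With the guides exchanged the counts were 130 of 239 (18.1), 81 of 147 (7.82) and 2 opposite (r = 0.420, covariance 0.108). Genes are not independent replicates, so these correlations carry no p-value. Fold changes also correlated negatively with transcript length in each of these comparisons, and that trend was not taken out here.

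The Traf3 guides and IFNγ also moved genes in common. Between Traf3 guides under vehicle and IFNγ in control cells, which share the control vehicle libraries, 57 genes rose in both (10.3 for independent lists) and 49 fell in both (6.16), with 25 opposite (15.9). The covariance of fold changes was 0.0930 against 0.0444 (0.0388 to 0.0491) in 20 simulated draws of unchanged groups, a difference of 0.0486, and r was 0.297 against 0.582. Simulated overlaps averaged 0.2 genes higher and 0.1 lower. Unchanged groups give few calls, so these overlaps were bound to be small. They set no level against which the overlap of the real calls can be judged. The 2 control libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. With no library in common, sgTraf3-1 under vehicle and IFNγ in sgTraf3-2 cells shared 57 higher genes (38.1 for independent lists) and 40 lower genes (19.2) with 47 opposite (57.7; covariance 0.0452), and with the guides exchanged 83 (44.6), 58 (25.6) and 79 opposite (69.0; covariance 0.0497). Opposite calls were thus above the count for independent lists in 2 of these 3 pairs, so part of the overlap may reflect genes that pass in any comparison. Fold changes in all of these comparisons correlated negatively with transcript length (rho from −0.0987 with sgTraf3-2 under vehicle to −0.440 for IFNγ in sgTraf3-2 cells). The overlaps were not recomputed with that trend taken out, so part of them may come from it.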

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

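Of the tests in this part, the corrections for length and GC, the fits without some libraries, the thinning, the NF-κB comparison between guides, the proteasome count with sgTraf3-1 alone and the tests of the large vehicle changes were chosen only after the results were seen.

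A difference between groups marks every result here. The IFNγ response differed between Traf3-guide and control cells in 1433 genes, but in 2 with sgTraf3-1 alone against 2897 with sgTraf3-2, in 25 without control IFNγ replicate 1 and in 1 with the guides taken as replicates. It also differed in the constitutive proteasome list (adjusted p = 1.17e-06), which did not pass with an estimated correlation (adjusted p = 0.818). Of its 24 members 14 were called, and 3 with the length and GC trend taken out. Named genes with such differences were Tapbp (−1.04), Ddx58 (−1.10), Parp10 (−1.01), Nlrc5 (−1.66), H2-K1 (−0.74), Lims2 (−1.31) and Tnfrsf14 (−5.68), with smaller fold changes over vehicle in Traf3-guide cells. Those with larger ones were Tgtp2 (3.76), Sp3os (1.40), Isg15 (1.27), Ifi47 (1.26), Dlx6os1 (1.24) and Ptpn18 (1.18). Tapbp and H2-K1 were higher with Traf3 guides under vehicle and under IFNγ, so their smaller fold changes do not mean lower levels. Tnfrsf14 lay at 0 counts in control vehicle libraries and Tgtp2 at 1 count in total in the Traf3-guide vehicle libraries, so their values depend on the prior count and measure no size. The cells of the 2 Traf3 guides differed from each other in 10 genes under vehicle and in 2027 under IFNγ.

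The first pattern is the distance between the guides under IFNγ. With each library's trend with length and GC content taken out, 1692 genes still differed, which argues against that trend as the whole cause. Thinning all libraries to the smallest total gave 2029, but the mean totals of the guides were nearly equal (19803456 and 20284852), so this test could not have come out otherwise and decides nothing about depth. A stronger loss of TRAF3 function with sgTraf3-2 may lie behind the difference, and would place NF-κB genes lower in sgTraf3-1. Their median difference was −0.119 over 10 genes under IFNγ, between the values set for and against it. Under vehicle, for which no such values were set, the median was −0.255 with 0 genes called. A stronger loss with sgTraf3-2 thus stays open, and the design cannot separate it from another difference between the lines or cultures.

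A further pattern is the rise of constitutive proteasome genes with Traf3 guides under IFNγ, where 19 of 24 were higher. With the length and GC trend taken out, 11 of 24 were higher and the median fell from 0.45 to 0.14, so the trend may account for much of the size of the rise while leaving part of the calls. With sgTraf3-1 alone 11 of 24 were higher (median 0.24) and with sgTraf3-2 20, but with the trend taken out 3 (median 0.08) and 16. The correction would also remove a real change that follows length or GC. It therefore cannot decide how far sgTraf3-1 supports the rise. A state of the IFNγ libraries labelled sgTraf3-2 cannot be told apart from an effect of both guides, since the count with sgTraf3-1 lay between the values set for and against it. A biological rise in proteasome genes stays open and was not tested further.

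The last pattern is the large changes with Traf3 guides under vehicle, such as Frmpd1, Stum and Carmil2. Of the 87 genes called with a change of at least 2-fold, 69.0% were called in the same direction with each guide alone and all 87 had the same sign with both. These genes were chosen by the mean of both guides, and the single-guide comparisons share the control vehicle libraries. Such agreement is therefore partly built in, and an event private to the cells of 1 guide stays open. The state of the control line cannot be told apart from an effect of Traf3 guides, since there is 1 control guide. That the libraries labelled sgTraf3-2 share these changes without a lower Traf3 mRNA may mean that TRAF3 protein was lost there too, which these data do not measure.

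For IFNγ in Traf3-guide cells, 1 of 35 splits of the 8 libraries into 4 and 4 gave as many genes. The real split gave 6626 in a model of the sides alone and the highest other split 1. Every other split puts vehicle and IFNγ libraries on both sides, so the IFNγ effect enters its spread and few calls could result. This test therefore decides nothing about chance as the source of that count.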

How the results depend on the processing

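The length and GC offsets, the fits without the IFNγ libraries labelled sgTraf3-2 and the thinning were chosen only after the data were seen. The counts for Traf3 guides under vehicle (411), Traf3 guides under IFNγ (5247), IFNγ in control cells (1012), IFNγ in Traf3-guide cells (7617) and the interaction (1433) stayed within 1.5 times under DESeq2 size factors, upper-quartile factors, DESeq2 (460, 4916, 1104, 7245 and 1708), limma-voom (440, 5259, 1120, 7616 and 1495), both filters and limma-trend on the deposited table (408, 5006, 946, 7312 and 1365). Upper-quartile factors changed the split of IFNγ in control cells to 518 higher and 569 lower (47.7% higher against 55.8%). Counts that moved further were as follows, and the cause was not tested except where fewer samples or a stricter threshold make it plain. With a 2-fold threshold added they were 87, 256, 187, 540 and 38, with 4 and 61 for the guides against each other under vehicle and IFNγ, and 56 and 87 for both guides. With the guides taken as replicates of a genotype, the count was 169 for Traf3 guides under vehicle, 369 for IFNγ in control cells and 1 for the interaction, since differences between guides then count as spread. With only the compared groups, IFNγ in control cells gave 619. Offsets gave 620 for Traf3 guides under vehicle, 721 for the interaction (51.2% higher against 69.0%), 1007 for both guides under IFNγ and 39 for the guides against each other under vehicle, where DESeq2 gave 48. With sgTraf3-1 alone the counts were 206, 1659, 4634 for IFNγ and 2 for the interaction, and with sgTraf3-2 alone the interaction gave 2897. Without the IFNγ libraries labelled sgTraf3-2 they were 2276, 4910 and 2. Of the list tests 31 passed, 13 with an estimated correlation and 50 with fry, which does not compare a list with other genes. Offsets also gave 31, with 3 calls lost and 3 gained. The calls lost were the proteasome list for Traf3 guides under vehicle, fibroblast markers for IFNγ in control cells and melanocyte genes for IFNγ in Traf3-guide cells. With sgTraf3-1 alone 34 passed, 0 lost and 3 gained, and with sgTraf3-2 alone 28, with 4 lost and 1 gained. The correlation across guides was 0.493 with the stricter filter and 0.562 with the guides exchanged. The overlap of Traf3 guides and IFNγ was 106 genes, and 97 and 141 with no library in common.

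Leaving out each library in turn gave 142 to 510 genes for Traf3 guides under vehicle, 2431 to 5576 under IFNγ, 311 to 1437 for IFNγ in control cells, 6857 to 7656 in Traf3-guide cells and 25 to 2485 for the interaction. It gave 74 to 187 and 121 to 2070 for both guides under vehicle and IFNγ, 2 to 35 and 178 to 2426 for the guides against each other, and 29 to 33 list calls. Of 4896 values of named genes in these fits, 4489 counted as kept, 373 lost the call and 28 gained it. A further 6 without a call changed sign with a shift of at least their SE in the main fit. Kept values held their direction and side of the threshold, or had no call and a sign change with a shift smaller than that SE. DESeq2 kept 381 of 389, limma-voom 385 of 396, the 4-group model 304 of 396 and the offsets 349 of 408. Of the called values, B2m with Traf3 guides under IFNγ (−0.19) and Slc24a5 with IFNγ in Traf3-guide cells (−0.13) changed direction with the offsets. A further 4 values without a call changed sign there with a shift of at least their SE. The cause of these changes was not tested.

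Replicate numbers do not pair the samples: deviations of same-numbered libraries correlated between −0.0531 and 0.1005 over 15 pairs of groups (median 0.00205). With a replicate block the counts were 411, 5219, 1001, 7605 and 1480, with 8 and 2015 for the guides against each other, 151 and 1576 for both guides and 30 list calls, and 8 of 408 calls of named genes changed. Depth limits genes near the floor of 0.120 to 0.185 CPM, and at the spread between these replicates 37.3% of genes simulated with a 1.5-fold interaction were called with sgTraf3-1 alone. The shares were 80.6% at 2-fold and 95.5% at 4-fold.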

Other observations

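The gene families in this part and their tests were chosen only after the data were seen, so they are not independent evidence. Genes of the PARP family of ADP-ribosyltransferases rose with the Traf3 guides under vehicle, 6 of 12 higher and 0 lower (median log2 fold change 0.39, adjusted p = 1.10e-06; adjusted p = 0.0103 with an estimated correlation). Parp14 was at 0.97, Parp12 at 0.81, Parp3 at 0.71, Parp9 at 0.69, Parp10 at 0.65 and Parp8 at 0.62. With each guide alone 5 were higher. IFNγ in control cells raised 6 of 12 (median 0.77, adjusted p = 2.89e-10), and the interaction was negative for 6 (median −0.30, adjusted p = 0.000755; adjusted p = 0.0410 with an estimated correlation), including Parp14 (−0.82) and Parp12 (−0.61). For the interaction 0 were called with sgTraf3-1 alone (adjusted p = 0.000518; adjusted p = 0.0308 with an estimated correlation) and 6 with sgTraf3-2 (adjusted p = 0.00228; adjusted p = 0.0985 with an estimated correlation). With Traf3 guides under IFNγ 3 were higher and 2 lower (adjusted p = 0.489). Parp9 and Parp14 also belong to the IFNγ response list.

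The interferon-inducible GTPases, 13 genes that overlap the IFNγ response list, all rose with IFNγ in control cells (median 7.84) and in Traf3-guide cells (median 8.56). With Traf3 guides under IFNγ 8 were higher than in control (median 0.45, adjusted p = 0.0196; adjusted p = 0.254 with an estimated correlation), and the interaction called 2 (median 0.26, adjusted p = 0.00128; adjusted p = 0.0410 with an estimated correlation). With sgTraf3-1 alone it called 0 (adjusted p = 0.000487; adjusted p = 0.0308 with an estimated correlation). With sgTraf3-2 alone it called 1 (adjusted p = 0.00916; adjusted p = 0.0985 with an estimated correlation). Tgtp1 and Tgtp2 lay at 1 count each and Iigp1 at 2 in the Traf3-guide vehicle libraries, so such members' interactions depend on the prior count. Collagen and laminin genes fell with IFNγ in control cells, 8 of 30 lower and 0 higher (median −0.50, adjusted p = 1.70e-07; adjusted p = 0.0240 with an estimated correlation), among them Lama5 (−1.03), Lamb1 (−0.86), Col5a1 (−0.84) and Col4a2 (−0.74). In Traf3-guide cells 13 were lower (median −0.65, adjusted p = 0.000186; adjusted p = 0.0887 with an estimated correlation). Fold changes correlated negatively with transcript length across genes in both comparisons (Spearman rho −0.260 and −0.373). No value with that trend taken out is given for the collagen and laminin genes, so part of their fall may follow it. Ribosomal protein genes were higher with Traf3 guides under IFNγ in 72 of 92 cases and lower in 3 (median 0.52, adjusted p = 2.76e-15; adjusted p = 0.361 with an estimated correlation), 30 with sgTraf3-1 alone and 74 with sgTraf3-2, and mitochondrially encoded genes in 12 of 15 (median 0.43). These are short transcripts in libraries with a length trend.

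Among the genes with a smaller IFNγ fold change with Traf3 guides, some were already higher under vehicle, and their levels under IFNγ did not follow a common course. The examples were picked from genes called for a negative interaction. Ddx58 stood at 4.28 ± 0.166 CPM in control and 10.3 ± 1.30 CPM with Traf3 guides under vehicle (SD, n = 2 and n = 4), and at 31.4 ± 4.99 and 34.9 ± 2.27 CPM under IFNγ. Csf1 went from 18.9 and 32.4 CPM to 60.5 and 59.0 CPM. Parp10 went from 9.15 ± 0.412 and 14.5 ± 1.43 CPM to 86.7 ± 3.03 and 67.8 ± 6.96 CPM, ending lower with Traf3 guides, while Tapbp (276 and 360 CPM) and H2-K1 (140 and 446 CPM) stayed higher under IFNγ.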
